A study of Homo sapiens with 20 samples.

How the data were processed

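Total RNA of HEK-TLR2 cells was labelled with biotin and hybridised to Affymetrix expression arrays, per the labels' protocols. There were 20 arrays in 10 groups of 2, with and without 10 µg/ml H. pylori LPS at 2, 4, 8, 24 and 48 h. Groups and replicate numbers were taken from the sample titles and source names. The deposited table holds 1 log2 expression value per probe set and array, summarised and normalized by the authors. The submitters' processing notes name MAS5 and RMA, with no version and no role, and the scale and the nearly equal distributions of the arrays look like those of RMA; the genome build is not given in the sources used here. Array medians lay between 5.08 and 5.14. No total or detection call was used, so the number of arrays, not a depth, limits the precision.

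Of 54675 probe sets, 62 were controls and were left out. A table of GEO's platform annotation named 1 gene for 41091 probe sets, several for 1801 and none for 11721, and 41037 matched the reference gene table by gene ID, from which current symbols were taken. Each of 19775 genes was represented by the probe set, among those naming only that gene, with the highest mean over the 20 arrays; 10523 genes had several. No coordinates were used. The deposited values were not normalized again, and no filter on dim genes was used.

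Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust) in 1 fit of group means over all 20 arrays, which shares 1 estimate of the spread with 10 residual degrees of freedom and a prior of 5.51 degrees of freedom. P-values were adjusted by Benjamini and Hochberg over all genes within a comparison, with a threshold of 0.05. There were 10 comparisons: LPS against untreated cells at each of the 5 times and as their mean, the difference of the LPS effect between times, the late minus early effect, and untreated cells at any time and at 48 h against 2 h. All tests were two-sided, F tests apart. The 27 gene lists held 894 distinct genes, of which 802 were measured, and were tested with camera at a preset correlation of 0.01 in 7 comparisons, with camera at an estimated correlation and with fry beside it; adjustment was over the lists of a comparison. Each list also got its count of members passing over all genes and adjusted over the list alone. Groups, comparisons, tests, lists, the rule for named genes and other ways of fitting were fixed before the data were examined.

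The labels give the same replicate numbers in every group, and the series' design text states 2 independent experiments. That the numbers are these experiments is not given in the sources used here. It was checked whether the numbers pair the arrays: the deviations of replicates from their group means, correlated across genes between untreated and LPS cells of a time, had r of 0.58, 0.35, 0.46, 0.36 and 0.52 at 2, 4, 8, 24 and 48 h, and between 0.26 and 0.68 over all pairs of groups. These are correlations across genes, which are not independent replicates. The first principal component also separated the numbers. The fit with the replicate number as an additive term (9 residual degrees of freedom, prior 11.4) is therefore given beside the fit without it where it changes a call. Within groups, replicates correlated across genes with r from 0.985 to 0.993 and no 2 arrays were identical.

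Named genes were chosen by rule: per comparison and direction up to 10 genes with the largest difference among those called, with arrays of the groups apart; where fewer passed, genes of smallest p fill up to 10 and are given as values. For the difference between times the 10 genes of smallest p are named, for each list up to 4 members of smallest p, and in addition 20 preset genes of the receptor complex, the Tribbles family, inflammation and stress. List members that passed adjusted over the list alone, and genes called without certain arrays, were named after their values were seen.

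Those other ways were the replicate number as a term, overall or within each time; an intensity trend or a robust prior; quantile normalization or centring of each array; genes at or above the median level only; the mean of a gene's probe sets or all probe sets; array weights; the 4 arrays of a time alone; and leaving out each array in turn. Repeats of these with the replicate term, a fit with the replicate term and the 3′ minus 5′ signal of actin and GAPDH as a covariate, and fits without the 48 h arrays, were added after the data were seen. Other splits of the arrays were drawn 100 times with a fixed seed. The scripts were tested on simulated data for LPS against untreated at 8 h over 19775 genes, with 50 genes changed at each of 4 sizes: without the replicate term 14% of changes of 0.5 on the log2 scale were recovered, 68% of those of 1, 98% of those of 2 and 100% of those of 3, and with it 38%, 96%, 100% and 100%. Of 19545 unchanged genes 1 and 9 were called. A list shifted by 0.5 had an adjusted p of 2.72e-20 at the preset correlation, 0.0353 at an estimated one and 0.0819 by fry without the term, and 8.16e-24, 2.39e-05 and 2.13e-07 with it. The simulated noise was normal and independent between genes, and all changes were made in the same data. Real genes vary together and fewer were called, so these shares and list p-values may not hold for the real data. Figures were drawn with matplotlib 3.10.9.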

Results

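Messenger RNA levels were measured in HEK-TLR2 cells, a human embryonic kidney line that carries a stable TLR2 transgene. TLR2, Toll-like receptor 2, is a cell-surface receptor for bacterial products. The medium was replaced either with fresh medium or with medium holding 10 µg/ml lipopolysaccharide (LPS), the outer-membrane glycolipid of Gram-negative bacteria, here from Helicobacter pylori. Cells were harvested 2, 4, 8, 24 and 48 h later. This gave 10 groups of 2 Affymetrix arrays, numbered replicate 1 and replicate 2, and the series' design text states 2 independent experiments. The deposited log2 values were used for 19775 genes, and the median of an array lay between 5.08 and 5.14. With 2 arrays per group, the number of arrays limits the precision.

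TLR2, the transfected receptor, was expressed at different levels in the arrays of each replicate number. Its log2 value was 7.49 ± 0.38 (SD, n = 10 arrays) in replicate 1 and 5.82 ± 0.17 (SD, n = 10) in replicate 2, which was 3.17-fold lower (limma, adjusted p = 9.85e-11 over all genes). CXCL8, which encodes the neutrophil attractant interleukin-8, was lower in replicate 2 by the same test (log2 difference -1.87, adjusted p = 1.21e-06), and so was NFKBIA, the inhibitor that holds NF-kB in the cytoplasm (-1.09, adjusted p = 2.20e-06). Each replicate number may be a single experiment, so these p-values measure the spread among arrays and not that between experiments. TLR2 did not pass the test for LPS, with a mean difference over the 5 times of 0.11 (SE 0.43, limma, adjusted p = 0.977; SE 0.09 and adjusted p = 0.559 with the replicate number as a term). The main component of variation among the 20 arrays, which held 32.3% of the variance, separated the replicate numbers. The fit fixed before the data were examined had no term for the replicate number. The fit with that term, an alternative fixed at the same stage, is given beside it wherever it changed a call.

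**Figure D1:**
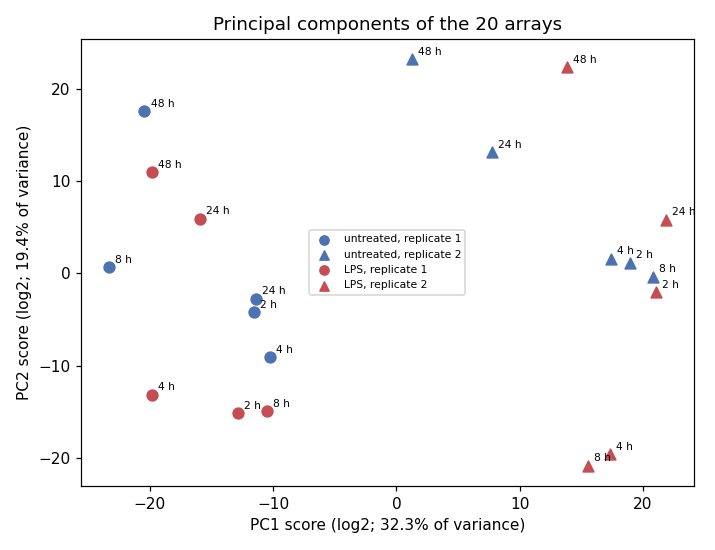
Scores of the 20 arrays on the first and second principal components of the 19775 genes (log2 values; colour gives the treatment, shape the replicate number and the text the time). All arrays of replicate 2 lie at or above 1.28 on the first component and all of replicate 1 at or below -10.2.

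The first comparison asked which genes responded to H. pylori LPS in these cells, taking the LPS minus untreated difference as the mean of the 5 times. CXCL8 was the 1 gene called, and only with the replicate number as a term. Its values were 2.80-fold higher with LPS (log2 difference 1.49), higher in 5 of 5 pairs of arrays in replicate 1 and in 4 of 5 in replicate 2. Within replicate 1 the mean LPS difference of CXCL8 was 1.65 ± 1.17 (SD, n = 5 times) and within replicate 2 it was 1.32 ± 2.49. In that fit CXCL8 passed the test (SE 0.20, limma, adjusted p = 0.00649), but its LPS and untreated arrays were not apart at every time. At 2 h they overlapped, with 7.88 and 5.76 with LPS against 6.62 and 4.20 without. Chance was not excluded for this count, since 8 of 100 exchanges of treatment within pairs, the real one included, called as many. Without that term the same difference had an SE of 0.53 and an adjusted p of 0.646, and limma called 0 genes, with 1453 genes at an unadjusted p under 0.05. Of 100 splits of the arrays within times, the real one included, 23 gave at least 1453 such genes, with 5300 as the highest. These splits ignored the replicate number, so they could set replicate 1 against replicate 2 and cannot gauge chance for this count. With the replicate term 2888 genes had an unadjusted p under 0.05. The call of CXCL8 was lost without the LPS 24 h array of replicate 1 (adjusted p = 0.0597), with a robust prior (0.168), after quantile normalization (0.0502) and with all probe sets tested, where the count was 0. It was also lost with the 3′ minus 5′ signal of actin and GAPDH, a sign of RNA quality, as a covariate chosen after the data were seen: the difference was then 1.42 (SE 0.23, adjusted p = 0.0993), with 0 genes called and 1394 at an unadjusted p under 0.05. The count of 1 became 53 without the untreated 24 h array of replicate 1, 14 without the LPS 8 h array of replicate 1, 6 and 2 without the untreated 48 h arrays of replicates 2 and 1, 3 without the LPS 48 h array of replicate 2, and 2 without the untreated 2 h array of replicate 2 or the LPS 4 h array of replicate 1.

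The 48 h arrays of replicate 2 stood apart for these genes, as given with the 48 h comparison, so the fit with the replicate number was repeated without them, an alternative chosen after their values were seen. Leaving out all 48 h arrays, the mean LPS difference of the other times was called for 8 genes. CXCL8 (2.10, limma, adjusted p = 5.42e-11), CCL20 (0.93, 2.43e-06), CXCL2 (0.79, 0.000637) and CXCL1 (0.66, 0.0168), all of them chemokines, rose. So did IER3, an early response gene (0.72, 0.00298), NFKBIA (0.51, 0.00438) and SELE, the adhesion molecule E-selectin (0.66, 0.0302). POLK, a DNA polymerase for damaged templates, fell (-0.65, 0.00438). Since these arrays were left out because of values of the same genes, the counts are not independent evidence. Leaving out only the pair of 48 h arrays of replicate 2 gave 7 genes.

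**Figure D2:**
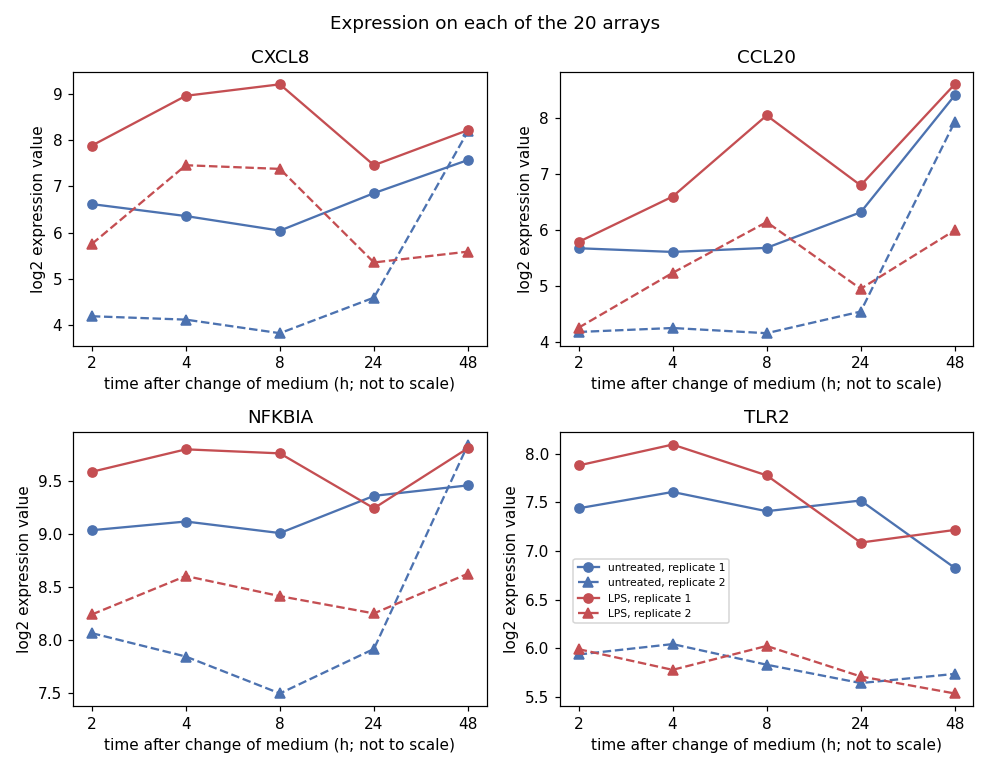
Log2 expression of CXCL8, CCL20, NFKBIA and TLR2 on each of the 20 arrays by time after the change of medium (times evenly spaced, not to scale; colour gives the treatment, line and marker the replicate number; each point is 1 array). CXCL8 reached 9.20 and 7.38 with LPS at 8 h against 6.04 and 3.83 without, and the untreated 48 h array of replicate 2 lies at 8.19 for CXCL8 against 5.59 on its LPS partner.

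Among the genes fixed beforehand, those of the receptor complex and its adaptor did not pass the test for the mean of 5 times. The log2 differences were -0.15 for TLR1, -0.04 for TLR6, -0.04 for TLR4, 0.02 for LY96, 0.07 for CD14 and 0.00 for MYD88, the adaptor of Toll-like receptors. Apart from MYD88 (mean log2 value 7.09), these genes lay below the array medians: LY96 at 2.74, TLR1 at 2.96, CD14 at 3.40, TLR4 at 4.20 and TLR6 at 4.24. No detection call was used, so these 5 may not have been expressed, and differences near 0 do not show that LPS left them unchanged. The Tribbles pseudokinases TRIB1, TRIB2 and TRIB3 differed by 0.02, 0.00 and 0.09. For TRIB2 the mean of the pairs was -0.14 ± 0.07 in replicate 1, with 0 of 5 pairs higher, and 0.14 ± 0.20 in replicate 2, with 4 of 5 higher. For TRIB3 the mean of the pairs was -0.03 ± 0.26 in replicate 1 and 0.20 ± 0.15 in replicate 2 (SD, n = 5). NFKBIA differed by 0.32, TNFAIP3, the NF-kB inhibitor A20, by 0.18, ATF3 by 0.22, EGR1 by 0.09 and FOS by -0.10, these last being early response transcription factors. The stress genes DDIT3, ASNS and HSPA5 differed by 0.07, 0.19 and 0.10 and the interferon-induced chemokine CXCL10 by -0.08. Genes of smallest p in the fit without the replicate term, none of which passed the test, had positive log2 differences in PAPSS1 (0.28), MAD1L1 (0.39), FAM174C (0.32), CCDC85B (0.39), TOP3B (0.31), RXYLT1 (0.43), OBSL1 (0.32), ZMYND8 (0.26), SRPX (0.24) and PES1 (0.28). Negative differences of smallest p were those of CPVL-AS2 (-0.40), LINC00589 (-0.30), ZNF571-AS1 (-0.24), LOC101927552 (-0.29), LOC100130357 (-0.30), KRT2 (-0.40), DPP6 (-0.31), NUP50-DT (-0.23), CILP (-0.28) and TLR10 (-0.33). PAPSS1 makes the sulfate donor of the cell, MAD1L1 acts in the spindle checkpoint, PES1 in ribosome assembly, KRT2 is a keratin and TLR10 is a Toll-like receptor.

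Gene lists fixed beforehand were tested over the mean of 5 times with limma's camera at a preset correlation. At that setting 5 of 27 lists were higher with LPS, and none of these calls held with an estimated correlation. Of 44 measured ATF4 targets, genes of amino acid supply and transfer RNA charging, 40 had a positive difference (median 0.13, adjusted p = 1.18e-06; 0.606 with an estimated correlation), among them PCK2 (0.21), NUPR1 (0.31), GARS1 (0.22) and SARS1 (0.20). Ribosome biogenesis (34 of 36 positive, median 0.11, adjusted p = 9.97e-06; PES1 0.28, RRP9 0.25), replication genes of the G1/S transition (40 of 47, median 0.08, 0.000223; CHAF1B 0.24, POLD3 0.18), cholesterol synthesis (23 of 25, median 0.09, 0.00230; EBP 0.22, TM7SF2 0.19) and hypoxia and glycolysis (37 of 41, median 0.08, 0.0333; ENO2 0.23, ANGPTL4 0.22) had the same direction. With an estimated correlation their adjusted p was 0.606, and 0.723 for hypoxia, and fry called 0 lists. Much of the hypoxia difference came from the 48 h pair of replicate 2: its mean over the 10 pairs was 0.08, and 0.04 without that pair, against 0.12 and 0.08 for ATF4 targets. At the preset correlation 8 lists were called without the LPS 2 h or the LPS 8 h array of replicate 1, or the untreated 4, 8 or 48 h array of replicate 2. No member passed over all genes, and adjusted over the list alone 0 ATF4 targets and 1 ribosome biogenesis gene passed without the replicate term, against 5 (SLC7A5, NUPR1, GARS1, SARS1 and PCK2) and 1 (PES1) with it. With that term 7 lists were called, with NF-kB targets higher (25 of 30 positive, adjusted p = 0.000668 against 0.0759 without the term; 0.550 with an estimated correlation) and ribosomal proteins lower (5 of 51 positive, 0.00927; 0.730 with an estimated correlation). For ribosomal proteins the mean differences at 2, 4, 8, 24 and 48 h were -0.12, -0.21, 0.15, -0.08 and -0.13 in replicate 1. They were -0.002, 0.02, -0.01, 0.07 and 0.03 in replicate 2, so the lower values were mainly those of replicate 1. Adjusted over the list alone, 6 NF-kB targets passed in the fit with the replicate term: CXCL8, CCL20, CXCL2, IER3, CXCL1 and PTX3. Of these CXCL1 had a mean difference of 0.95 in replicate 1 and -0.01 in replicate 2, where 2 of 5 pairs were higher, and CXCL2 one of 0.90 and 0.16.

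At 2 h CXCL8 was the NF-kB target furthest above its untreated level, 2.66-fold higher with LPS (log2 difference 1.41; 1.26 and 1.56 within replicates 1 and 2), and it did not pass the test. Limma called 0 genes, with 203 at an unadjusted p under 0.05, and 0 with the replicate number as a term, with 563. Without the 48 h arrays, left out after their values were seen, CXCL8 was called (adjusted p = 0.00321), and the count was also 1 without either untreated 48 h array. The genes of smallest p had positive differences in PPP2R2C (0.59), TMEM52 (0.58), CCL22 (0.45), ADRA1D (0.50), GFRA3 (0.60), ZNF663P (0.56), PITPNM1 (0.46), MYH7B (0.68), RGMB-AS1 (0.47) and ZNF830 (0.41). Negative differences of smallest p were those of LINC01560 (-0.81), CPVL-AS2 (-0.68), POLR1HASP (-0.62), RBM47 (-0.63), GJA4 (-0.46), MARK2 (-0.45), GNAO1-DT (-0.41), FAM47E (-0.39), POLR3A (-0.44) and ZNF827 (-0.60). CCL22 is a chemokine and ADRA1D an adrenergic receptor. No gene list was called, but 5 were without the LPS 2 h array of replicate 2, 2 without either untreated 2 h array and 1 without the LPS 2 h array of replicate 1. With genes at or above the median level alone 2 were called. With the replicate term ribosomal proteins were lower (8 of 51 positive, camera, adjusted p = 0.00236, and 0.947 with an estimated correlation). Their mean difference was -0.12 in replicate 1 and -0.002 in replicate 2.

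At 4 h the chemokine genes CXCL8, CXCL2, CXCL1 and CCL20 had higher values with LPS in both replicates. With the replicate number as a term CXCL8 alone passed over all genes. It rose 7.80-fold (log2 2.96, SE 0.45, limma, adjusted p = 0.0348; 2.60 and 3.33 within replicates 1 and 2), from 5.24 ± 1.58 to 8.21 ± 1.06 (SD, n = 2). CXCL2 (1.31), CXCL1 (1.08), CCL20, an attractant of lymphocytes and dendritic cells (0.99), and TNFAIP3 (0.74) passed in the same fit when adjusted over the list alone, as 5 of 30 NF-kB targets against 1 over all genes. Of these 30 genes, 25 had a positive difference (median 0.22, mean 0.40). The list was higher by camera (adjusted p = 0.00945; 0.992 with an estimated correlation), by 0.45 in replicate 1 and 0.36 in replicate 2. Without the replicate term limma called 0 genes, with 600 at an unadjusted p under 0.05, and CXCL8 had an SE of 1.18; with it the count was 1, with 1533. That call was lost without any 1 of the 4 h arrays, of the 24 h arrays or of the untreated 8 h arrays, with a robust prior (adjusted p = 0.484), quantile normalization (0.196), array weights (0.185) the mean of both CXCL8 probe sets (0.228) or all probe sets, where the count was 0. With the 3′ minus 5′ covariate CXCL8 differed by 2.92 (SE 0.46, adjusted p = 0.0716), with 0 genes called and 1366 at an unadjusted p under 0.05. The second CXCL8 probe set differed by 1.49. The count was 2 without either untreated 48 h array and 3 without all 48 h arrays (CXCL8, CXCL2 and CCL20). The genes of smallest p without the term had positive differences in COL25A1 (0.57), EPHA8 (0.59), AGER (0.84), IGF2-AS (0.68), KLF1 (0.50), TLX2 (0.58), FAM174C (0.51), TMEM204 (0.68), RASSF1-AS1 (0.53) and TADA3 (0.42). Negative differences of smallest p were those of HCG4B (-0.64), PIK3C2B (-0.63), FIZ1 (-0.69), A2M (-0.52), JHY (-0.53), CALHM1 (-0.53), ZNF649-AS1 (-0.48), PSMG3-AS1 (-0.61), CPA3 (-0.58) and DPP6 (-0.60). AGER is the receptor for glycation end products and A2M a protease inhibitor.

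Other lists called at 4 h were lost with an estimated correlation (adjusted p = 0.992, and 0.933 for the TXNIP list). They were ATF4 targets (32 of 44 positive, camera, adjusted p = 0.0146), replication genes (36 of 47, 0.0146) and ribosome biogenesis (30 of 36, 0.00945) on the higher side. Ribosomal proteins (3 of 51 positive, 0.00945) and the TXNIP list of glucose-sensing genes (4 of 21, 0.0263) were on the lower side. No member passed without the replicate term, and the number of lists fell from 6 to 2 without the untreated 4 h array of replicate 1. Within replicates 1 and 2 the mean differences were -0.21 and 0.02 for ribosomal proteins, 0.01 and 0.24 for ribosome biogenesis, 0.03 and 0.18 for ATF4 targets, 0.06 and 0.14 for replication genes and -0.15 and -0.11 for the TXNIP list.

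At 8 h the response of CXCL8 and CCL20 was highest. CXCL8 rose 10.2-fold (log2 3.35, SE 0.45, limma with the replicate number as a term, adjusted p = 0.00285; 3.16 and 3.55 within replicates 1 and 2), from 4.94 ± 1.57 to 8.29 ± 1.29 (SD, n = 2). CCL20 rose 4.53-fold (log2 2.18, SE 0.28, adjusted p = 0.00234; 2.37 and 1.99 within replicates), from 4.92 ± 1.08 to 7.10 ± 1.35. In the fit without that term their SEs were 1.18 and 0.96 and their adjusted p 0.641 and 0.670, and limma called 0 genes, with 1448 at an unadjusted p under 0.05 against 2927 with the term. Of 30 NF-kB targets 25 had a positive difference (median 0.32, mean 0.51), and the list was higher by camera (adjusted p = 0.00292; 0.794 with an estimated correlation), by 0.62 in replicate 1 and 0.40 in replicate 2. With the replicate term 2 of the 30 passed over all genes and 9 adjusted over the list alone: besides CXCL8 and CCL20 these were CXCL1 (1.31), PTX3, a soluble pattern receptor (1.17), CXCL2 (1.15), IER3 (0.93), NFKB2 (0.86), NFKBIA (0.83) and CXCL3 (0.72). Genes outside the NF-kB list also passed in that fit adjusted over their own list, in both directions, but not over all genes. Lower values were those of the cytokine IL1B (-0.68), IRAK3 (-0.46), CD200 (-0.57), HMOX1 (-0.65), COL5A1 (-0.47) and MS4A1 (-0.475). Higher values were those of CCL7 (0.56), IL32 (0.69), ATF5 (0.63), NUPR1 (0.95), HSPA4L (0.58), HSPB1 (0.51), ISG15 (0.57) and AQP2 (0.65).

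A sign of RNA quality differed between LPS and untreated arrays at 8 h in the same direction in both replicates. The 3′ minus 5′ signal was higher on the LPS array by 0.22 in replicate 1 and 0.29 in replicate 2, where the SD of the 20 arrays was 0.151. Differences of this size were not confined to 8 h. Within replicates 1 and 2 they were 0.28 and -0.002 at 2 h and -0.15 and 0.27 at 4 h. With that signal as a covariate beside the replicate number, CXCL8 differed by 3.16 (SE 0.56, limma, adjusted p = 0.182) and CCL20 by 2.11 (SE 0.35, adjusted p = 0.133). The differences stayed close to 3.35 and 2.18 and their SEs grew from 0.45 and 0.28, so that 0 genes were called, with 1004 at an unadjusted p under 0.05. Of the lists called at 8 h, NF-kB targets alone remained with the covariate (camera, adjusted p = 9.88e-09; 0.916 with an estimated correlation). The second CXCL8 probe set differed by 1.72 at 8 h, 0.00 at 24 h and 0.72 in the mean of 5 times.

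The calls of CXCL8 and CCL20 at 8 h were lost without the untreated 8 h array of replicate 1 (adjusted p = 0.0755 for both; 0 genes called, with 1410 at an unadjusted p under 0.05), and that of CXCL8 with a robust prior (0.103). The count of 2 was 83 without the LPS 8 h array of replicate 1, 24 without the untreated 8 h array of replicate 2, 9 without either LPS 4 h array, 5 without either LPS 2 h array, 4 without the LPS 8 h array of replicate 2 and 4 without all 48 h arrays. In the fit without the replicate term the genes of smallest p had positive differences in FAM174C (0.69), SMPD3 (0.78), DIRAS1 (0.79), LINC02071 (0.58), WNT9A (0.55), NUPR1 (0.95), PLIN4 (0.86), CLECL1 (1.34), RFXANK (0.65) and ADGRD2 (0.86). Negative differences of smallest p were those of LOC105373418 (-0.76), ERCC4 (-0.83), DCHS2 (-0.60), COPB2-DT (-0.61), KRT2 (-1.04), NUP50-DT (-0.58), MIR670HG (-0.61), ARHGEF15 (-0.60), PAXBP1-AS1 (-0.72) and C18orf15 (-0.75). NUPR1 is a stress-induced nuclear protein, WNT9A a secreted signal and ERCC4 a DNA repair nuclease. Oxidative phosphorylation (47 of 50 positive, camera, adjusted p = 0.000335), ribosome biogenesis (33 of 36, 0.000632) and replication genes (35 of 47, 0.0286) were also higher, with adjusted p = 0.829, 0.794 and 0.829 with an estimated correlation, and all 3 calls were lost with the 3′ minus 5′ covariate. The number of lists was 2 without the untreated 8 h array of replicate 1, and 0 with genes at or above the median level alone, so the NF-kB call was lost there too. Within replicates 1 and 2 oxidative phosphorylation differed by 0.28 and 0.09, ribosome biogenesis by 0.15 and 0.21 and replication genes by 0.10 and 0.10.

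At 24 h CXCL8 and CCL20 differed less than at 8 h. CXCL8 differed by 0.68 (0.60 and 0.76 within replicates 1 and 2) and CCL20 by 0.44, and neither passed. Limma called 0 genes, with 169 at an unadjusted p under 0.05, and 0 with the replicate number as a term, with 535. NF-kB targets differed by -0.03 in replicate 1 and 0.19 in replicate 2. The genes of smallest p had positive differences in NRP2 (0.59), CAPZA3 (0.38), ICA1L (0.46), TNFRSF12A (0.56), EFNA3 (0.41), LOC101928626 (0.37), LBX1-AS1 (0.55), GCSIR (0.39), ZNF668 (0.42) and SLC39A1 (0.40). Negative differences of smallest p were those of MVP (-0.61), IRAG1-AS1 (-0.48), ARHGEF15 (-0.46), LCN1 (-0.57), CCDC116 (-0.54), KLRB1 (-0.49), ANHX (-0.44), FABP3P2 (-0.50), RTL3 (-0.47) and RGMB-AS1 (-0.44). NRP2 is a co-receptor for semaphorins and VEGF, TNFRSF12A the receptor of TWEAK and MVP the main protein of vault particles. Cholesterol synthesis was the 1 list called (19 of 25 positive, camera, adjusted p = 0.0478; 0.994 with an estimated correlation; FADS2 0.45, INSIG1 0.22), with a mean difference of -0.08 in replicate 1 and 0.27 in replicate 2. With the replicate term, or with genes at or above the median level alone, the count was 0. It was also 0 without any 1 of the 48 h arrays, the untreated 2 h arrays or the untreated or LPS 8 h arrays, and 9, 6 and 4 without the LPS 24 h array of replicate 1, the untreated one of replicate 1 and the LPS one of replicate 2.

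At 48 h the replicates went in opposite directions for NF-kB targets: the mean LPS difference of the list was 0.20 in replicate 1 and -0.59 in replicate 2. CXCL8 differed by 0.65 in replicate 1 and by -2.60 in replicate 2, CCL20 by 0.20 and -1.94, and NFKBIA by 0.35 and -1.22. Between the replicate numbers, replicate 2 minus 1, the LPS difference at 48 h differed by -2.14 for CCL20 and -3.24 for CXCL8. A test of this, added after these values were seen, had 1 array in each arm. It took its spread from the fit over all arrays, so it decides nothing here. In replicate 2 the untreated array held 8.19 for CXCL8 and 7.93 for CCL20, and the LPS array 5.59 and 6.00. Limma called 0 genes, with 342 at an unadjusted p under 0.05, and 0 with the replicate number as a term, with 983. With the term, 6 genes were called without the LPS 48 h array of replicate 1 and 3 without the untreated one of replicate 1. Genes of smallest p had positive differences in PLAUR (0.50), KIF1A (0.55), SEMA6A (0.53), MAST2 (0.45), ANTXR2 (0.49), ABL1 (0.41), PCK2 (0.49), MGAT4B (0.55), GAL3ST1 (0.47) and CARS1 (0.45). Negative differences of smallest p were those of SNRPF-DT (-0.64), LOC101928663 (-0.52), DUOX2 (-0.42), WDR86 (-0.48), NOX4 (-0.42), CCN3 (-0.62), BTNL3 (-0.44), BMP10 (-0.55), SYN3 (-0.50) and LPIN3 (-0.59). PLAUR is the urokinase receptor, PCK2 a mitochondrial enzyme of gluconeogenesis and NOX4 an oxidase that makes reactive oxygen.

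The list furthest from 0 at 48 h was that of ATF4 targets, of which 38 of 44 had a positive difference (median 0.26, camera, adjusted p = 4.86e-12; 0.667 with an estimated correlation). No member passed over all genes, and with the replicate term 8 passed adjusted over the list alone, against 0 without it: STC2, a secreted glycoprotein (1.00), ASNS, asparagine synthetase (0.67), CTH (0.61), CEBPB (0.59), PCK2 (0.49), AARS1 (0.47), GARS1 (0.45) and PHGDH (0.42). The shift was 0.09 in replicate 1 and 0.46 in replicate 2. Hypoxia and glycolysis had the same form (40 of 41 positive, adjusted p = 2.56e-05; 0.812 with an estimated correlation; 0.01 and 0.48 within replicates; ENO2 0.52, PFKFB4 0.41). Mitosis (35 of 42 positive, 0.000832), replication (38 of 47, 0.00998) and ribosome biogenesis genes (28 of 36, 0.0389) were higher, and cytokines (11 of 40 positive, 0.000832), NF-kB targets (8 of 30, 0.0337) and fibroblast markers (7 of 18, 0.0389) lower. None held with an estimated correlation (adjusted p = 0.812, and 0.667 for fibroblast markers), and the number of lists fell from 8 to 3 without the untreated 48 h array of replicate 1. Several held in 1 replicate alone: within replicates 1 and 2 cytokines differed by 0.06 and -0.37 and replication genes by 0.20 and -0.00. Mitosis genes differed by 0.16 and 0.07, ribosome biogenesis by 0.14 and 0.05 and fibroblast markers by -0.04 and -0.11.

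**Figure D3:**
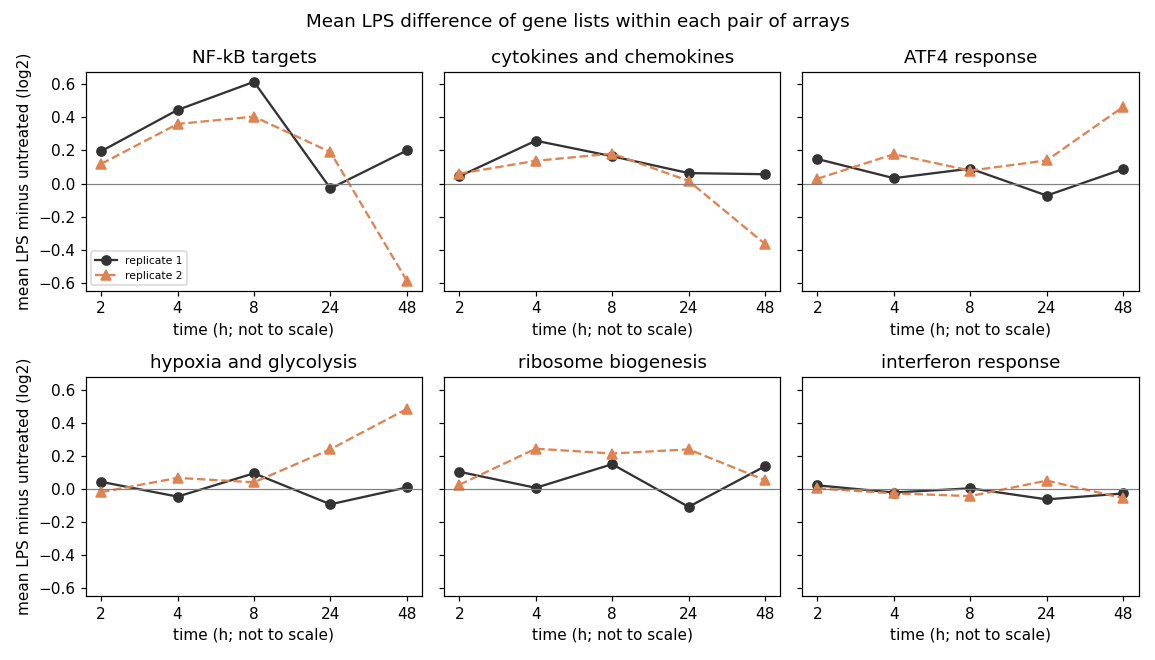
Mean LPS minus untreated log2 difference over the genes of 6 lists within each pair of arrays, by time (times evenly spaced, not to scale; 1 line per replicate number, and each point is the mean over the list's genes of 1 pair of arrays). NF-kB targets lie above 0 in both replicates at 2, 4 and 8 h, reach 0.62 and 0.40 at 8 h, and lie at 0.20 and -0.59 at 48 h.

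Whether the LPS response depended on time was asked with a test over all 5 times and with the late effect (24 and 48 h) minus the early one (2, 4 and 8 h). CXCL8 had a lower LPS effect late than early, by -2.72 on the log2 scale (SE 0.41, limma with the replicate number as a term, adjusted p = 0.0316), as 1 of 1 gene called; 1191 genes had an unadjusted p under 0.05. CCL20 differed by -1.30 and NFKBIA by -0.80, and neither passed. Without the term limma called 0 genes, with 416 at an unadjusted p under 0.05. The call of CXCL8 was lost on leaving out 15 of the 20 arrays 1 at a time, with adjusted p up to 0.345. It was kept without the untreated 2 h array of replicate 1, the LPS 4 h array of replicate 1, either untreated 48 h array or the LPS 48 h array of replicate 1. The count was then 4 without the untreated or the LPS 48 h array of replicate 1 and 2 without the LPS 4 h array of replicate 1. It also fell to 0 with a robust prior, quantile normalization, array weights, the mean of the probe sets or all probe sets. With the 3′ minus 5′ covariate the difference was -2.59 (SE 0.47, adjusted p = 0.443), with 0 genes called and 644 at an unadjusted p under 0.05. Without the 48 h arrays of replicate 2, a choice made after their values were seen, the difference was -1.91 (adjusted p = 5.95e-05). The test over all 5 times called 0 genes, with 161 at an unadjusted p under 0.05, and 0 with the replicate number as a term, with 835. In that fit CCL20 and CXCL8 had the smallest p (adjusted p = 0.0589 for both), and the count was 5, 2 and 1 without the untreated 48 h arrays of replicates 1 and 2 and the LPS one of replicate 1. In the fit without the term the genes of smallest p were HCG4B, TRIM17, SMPD3, RGMB-AS1, KIAA0513, LCN1, LINC02071, ARHGEF15, MVP and C18orf15, with late minus early differences from -0.67 (MVP) to 0.09 (KIAA0513).

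Untreated cells at each time gave the background to the LPS response, and their own course was compared between 48 and 2 h. CALCB and CALCA, which encode calcitonin gene-related peptides, rose 6.26-fold (log2 2.65, SE 0.26, limma, adjusted p = 0.000531) and 2.74-fold (1.45, SE 0.18, 0.00498), and CXCR4, the receptor of the chemokine CXCL12, rose 5.03-fold (2.33, SE 0.28, 0.00466). CCN2, a matrix protein also known as connective tissue growth factor, fell 5.00-fold (-2.32, SE 0.30, 0.00555), and CGA, the common subunit of glycoprotein hormones, fell 3.49-fold (-1.80, SE 0.30, 0.0347). RBM6 (1.29) and PPP4R4 (1.02) also rose. IRS1, an adaptor of the insulin receptor (-1.16), LARP1B (-1.13), PRSS23 (-0.99), RAB31 (-0.97), TIPARP (-0.88) and MICAL2 (-0.82) fell. In all, 13 genes were called, 5 higher and 8 lower, with 1471 at an unadjusted p under 0.05. Genes of smallest p past these were HILPDA (1.57), SGPP2 (1.17), SLC38A2-AS1 (0.59), HOXC6 (0.75) and WNT5A (0.84) on the positive side and SRSF6 (-0.94) and SYTL5 (-0.77) on the negative side. The count was 1 without the untreated 48 h or 2 h array of replicate 2, 2 and 7 without the 2 h and 48 h arrays of replicate 1, and 5 without either untreated 4 h array.

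Some of these calls rest on 1 of several probe sets of a gene. CALCA was called on a probe set at 1.45, and its 3 others differed by 0.06, 0.35 and 0.09. IRS1 had others at -0.02 and -0.25, PPP4R4 at -0.01 and -0.05, RBM6 at -0.32 and 0.19, CGA 1 at -0.03, and LARP1B 5 from -0.14 to 0.07. CXCR4 (1.03 and 1.22), RAB31 (-0.46 and -0.74), MICAL2 (-0.56, -0.20 and -0.24) and PRSS23 (-1.23, -0.06 and -0.50) had others in the same direction, and CALCB, CCN2 and TIPARP had a single probe set. With the mean of the probe sets limma called 4 genes, and 111 with the replicate number as a term.

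With the replicate number as a term, 208 genes were called between untreated 48 and 2 h, 58 higher and 150 lower, with 3016 at an unadjusted p under 0.05. All 13 genes called without it were among them. The highest differences were those of CCL20 (3.25, SE 0.28, limma, adjusted p = 9.49e-07), CALCB, CXCL8 (2.47, SE 0.45, 0.00961), CXCR4, DDIT4, an inhibitor of mTORC1 (2.19), TNFRSF9, a TNF receptor (1.99), HILPDA, a lipid droplet protein (1.57), PTX3 (1.52), HES5 (1.48) and CALCA. The lowest were those of CCN2, CGA, CCN1, a matrix protein (-1.52), COL12A1 (-1.46), EGR1 (-1.29), IRS1, LARP1B, ANXA3 (-1.12), ANXA1 (-1.08) and ETV5 (-1.03). Other probe sets of these genes differed by 1.09 for CXCL8, 0.97 and 0.54 for TNFRSF9, 1.07 for HILPDA, -1.04 for CCN1, -1.11 and -0.15 for EGR1 and 0.18 for ANXA1. They ranged from -0.88 to -0.09 for COL12A1 and from -0.99 to -0.01 for ETV5. The count was 15 without the untreated 48 h array of replicate 2, and all 15 were among the 208 (CCL20, CALCB, CCN2, CXCR4, CCN1, CGA, HAS2, CALCA, STEEP1, LARP1B, RBM6, ANXA1, SRSF6, BRPF1 and AFDN-DT). It was 72 without the untreated 48 h array of replicate 1, of which 58 were among the 208, 53 and 16 without the untreated 2 h arrays of replicates 1 and 2, of which 47 and 16 were, and 17 without both 48 h arrays of replicate 2, where CXCL8 did not pass (1.12, adjusted p = 0.0533). A test of any time against 2 h called 10 genes without the term, with 814 at an unadjusted p under 0.05, and 158 with it, with 2539. Without the term the 10 became 0 without the untreated 48 h array of replicate 2, 2 without that of replicate 1, either untreated 2 h array or the untreated 4 h array of replicate 1, and 3 without the untreated 4 h array of replicate 2. They became 4 and 5 without the untreated 24 h arrays of replicates 2 and 1, 5 without either LPS 4 h array and 6 without either LPS 2 h or LPS 8 h array. With the term the 158 became 24 and 65 without the untreated 48 h arrays of replicates 2 and 1, 97 and 105 without the untreated 4 h arrays of replicates 2 and 1, and 91 without the untreated 8 h array of replicate 1.

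By list, NF-kB targets were higher in untreated cells at 48 h than at 2 h: 23 of 30 had a positive difference (median 0.41, mean 0.63, camera, adjusted p = 5.10e-08; 0.307 with an estimated correlation). Without the replicate term no member passed over all genes and 1 adjusted over the list alone; with it 8 and 16 did, among them NFKB2 (1.36), IER3 (1.31), RELB (0.89), CCL2 (0.74) and TNF (0.71), all called over all genes. The shift was 0.36 in replicate 1 and 0.91 in replicate 2. Cytokines were higher too (31 of 40 positive, adjusted p = 8.29e-07; 0.307 with an estimated correlation), and with the replicate term this was the 1 list that held with an estimated correlation (adjusted p = 0.0464). That call was lost with the 3′ minus 5′ covariate (adjusted p = 0.0827 with an estimated correlation). Hypoxia and glycolysis genes were higher (33 of 41, 5.10e-08; 0.437 with an estimated correlation; 0.25 and 0.55 within replicates). With the term 1 member passed over all genes and 12 adjusted over the list alone, among them BNIP3 (1.23), BHLHE40 (1.15), P4HA1 (0.82) and VEGFA (0.80). Fibroblast markers were also higher (14 of 18, 0.000413; 0.130 with an estimated correlation; FBLN1 0.51, ACTA2 0.44).

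Lists of growth and protein folding were lower at 48 h than at 2 h. Ribosome biogenesis genes had 1 positive difference of 36 (median -0.34, camera, adjusted p = 1.70e-11; 0.307 with an estimated correlation; -0.31 and -0.38 within replicates). Of these, 3 passed adjusted over the list alone without the replicate term and 19 with it, among them NOP58 (-0.59) and MRTO4 (-0.59), both called over all genes. Genes of the unfolded protein response had 1 positive of 31 (median -0.29, adjusted p = 1.54e-09; 0.307 with an estimated correlation; -0.28 and -0.36 within replicates), with 5 and 11 passing adjusted over the list alone, among them CRELD2 (-0.71) and the chaperone genes DNAJB11 (-0.72) and HSPA5 (-0.71). Of 42 mitosis genes 0 had a positive difference (median -0.24, 1.54e-09; 0.347 with an estimated correlation). Without and with the replicate term 0 and 10 passed adjusted over the list alone, among them FOXM1 (-0.55), CDC20 (-0.48) and PLK1 (-0.37). Replication genes (9 of 47 positive, 0.00134; 0.437), heat shock genes (5 of 24, 0.00125; 0.375), NRF2 targets (8 of 30, 0.00432; 0.313), immediate early genes (15 of 42, 0.00432; 0.324) and YAP targets (9 of 25, 0.0379; 0.307) were lower as well, where the last value in each bracket is the adjusted p with an estimated correlation. CCN2 passed over all genes in both of the last lists, and with the replicate term CCN1 did too, with EGR1 and SPRED1 (-0.84) in the first of them and AMOTL2 (-0.92) in the second. IER3 (1.31), an immediate early gene, passed in that fit against the direction of its list. Fry called 0 of these 12 lists without the replicate term and 9 with it. The LPS comparison at 48 h and this one share the untreated 48 h arrays, so their opposite directions for NF-kB, cytokine and growth lists are not independent.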

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

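The tests of the 48 h arrays were chosen after the result was seen; the counts over other splits of the arrays were planned. CXCL8 was singled out because its LPS effect differed between late and early times, by -2.72 on the log2 scale (SE 0.41, limma with the replicate number as a term, adjusted p = 0.0316). Of 100 exchanges of treatment within the 10 pairs of arrays, the real one included, 8 called at least as many genes as the real 1, with 478 as the highest other count. Exchanging pairs of some times alone can turn an LPS effect common to all times into a difference between times. These exchanges therefore cannot gauge chance for this count, and chance was not excluded. The exchange with 478 swaps the 48 h pairs of both replicates and the 24 h pair of replicate 2. It therefore adds the LPS differences of early and late times in 9 of 10 pairs instead of opposing them, and what its calls stem from was not tested. For the mean LPS effect with the replicate number as a term, 8 of 100 exchanges called as many genes as the real 1, with 2 as the highest other, so chance is not excluded there either. At an unadjusted p under 0.05, a count read after the result was seen, 2 of 100 exchanges reached the real 2888 for the mean effect, with 3410 as the highest other, and 23 of 100 the real 1191 for the late minus early effect. That last count has the same limit as the calls for late minus early. In the fits without that term the real count was 0, which any split reaches (100 of 100), so those splits say nothing about chance. The highest other counts were 461 for the mean LPS effect and 4391 for the late minus early effect. Those splits could set arrays of replicate 1 against arrays of replicate 2.

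NF-kB targets were lower with LPS at 48 h in replicate 2, by -0.59 (SE 0.13 over genes; 4 of 30 genes higher), after being higher with LPS at 2, 4 and 8 h. A late fall with LPS was not seen in replicate 1, in which the list was higher with LPS at 48 h by 0.20 (SE 0.05 over genes, 24 of 30 genes higher). That value is from 1 pair of arrays, and an SE over genes does not measure variation between arrays. Exchanged labels of the pair of 48 h arrays of replicate 2 could give the lower values of replicate 2. The correlation between the replicates' LPS differences across genes outside the NF-kB and cytokine lists was 0.0939 at 48 h (r, across genes, which are not independent replicates), against -0.01, -0.00, 0.26 and -0.18 at 2, 4, 8 and 24 h, so the other genes carried little LPS difference shared by the replicates that would show an exchange. Exchanged and correct labels cannot be told apart. A difference between the replicates in the state of the cells at 48 h stays open and was not tested.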

How the results depend on the processing

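Fits that repeat an alternative with the replicate number as a term, those with the 3′ minus 5′ covariate and those without 48 h arrays were chosen after seeing the data; the others were planned. The results that answer a comparison were counts of genes or lists called. A count has no direction, so a reversal could not be seen in it, and the counts that moved are given below. Of 278 values of single genes, 31 of 834 changed sign under the replicate term, quantile normalization or the mean of the probe sets, and 153 of 5560 with 1 array left out. Without the replicate term, the 0 calls of each LPS comparison stayed 0 under the trend and robust priors, quantile normalization, centring, the filter on dim genes, the mean of the probe sets, all probe sets, array weights, and with any 1 array left out. The 4 arrays of a time alone, run for the 5 single times, also gave 0. Where not otherwise said, the cause was not tested. A fit with the replicate number within each time gives no comparison of untreated times, and an alternative for linear values was not run because the values are log2.

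The replicate number as a term (replicate block) moved the counts of called genes from 0 to 1 for the mean of 5 times, 1 at 4 h, 2 at 8 h and 1 for late minus early, and those in untreated cells to 158 for any time and 208 for 48 against 2 h; it moved the lists called at 2 h to 1 and at 24 h to 0. The replicate number within each time gave 3 genes for the mean, 1 at 4 h, 24 at 8 h, 2 for the difference between times and 1 for late minus early. Without the term, the counts for untreated cells at any time and at 48 against 2 h were 4 and 4 with the mean of the probe sets, 2 and 5 with all probe sets and 22 and 27 with array weights.

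With the replicate term, the counts for the mean of 5 times, 4 h, 8 h and late minus early (1, 1, 2 and 1) were as follows. The trend gave 5 for the mean, 4 at 8 h and 2 for the difference between times. The robust prior gave 0 for the mean, 0 at 4 h, 1 at 8 h and 0 for late minus early. Quantile normalization gave 0 for the mean, 4 h and late minus early. Genes at or above the median level, with fewer genes tested, gave 7 for the mean, 4 at 8 h and 2 for the difference between times. The mean of the probe sets gave 2 for the mean, 0 at 4 h, 4 at 8 h and 0 for late minus early; all probe sets gave 0 for the mean, 4 h and late minus early; array weights gave 0 at 4 h and for late minus early. For untreated cells at any time and at 48 against 2 h, the trend gave 378 and 572, the filter on dim genes 340 and 648, the mean of the probe sets 70 and 111 and array weights 426 and 1017. The 3′ minus 5′ signal as a covariate gave 0 for the mean, 0 at 4 h, 0 at 8 h and 0 for late minus early. Without the 48 h arrays the counts were 8 for the mean, 1 at 2 h, 3 at 4 h and 4 at 8 h; without both 48 h arrays of replicate 2 they were 7, 1, 3 and 4, with 2 for the difference between times, 29 for untreated cells at any time and 17 at 48 against 2 h.

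The lists called fell to 0 in every comparison with an estimated correlation and with fry, from 5 for the mean, 6 at 4 h, 4 at 8 h, 1 at 24 h, 8 at 48 h and 12 in untreated cells. With the replicate term they were 0 for LPS with an estimated correlation or fry, and in untreated cells 1 with an estimated correlation and 9 with fry. The mixed form of fry, which asks for changes in either direction, called 10 lists for the mean, 1 at 4 h, 5 at 8 h and 18 in untreated cells with the term, and without it 2 in untreated cells and 0 for LPS. With the replicate term and the 3′ minus 5′ covariate 8 lists were called for the mean, 2 at 2 h, 1 at 8 h and 3 at 24 h. The filter on dim genes gave 2 lists at 2 h, 0 at 8 h and 0 at 24 h.

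With 1 array left out, so that a lone array is assumed to vary like the other groups, the counts of genes with the replicate term ranged from 0 to 53 for the mean, 0 to 1 at 2 h, 0 to 2 at 4 h, 0 to 83 at 8 h, 0 to 6 at 48 h, 0 to 5 for the difference between times, 0 to 4 for late minus early, 24 to 181 for untreated cells at any time and 15 to 271 at 48 against 2 h. Without the term the last pair ranged from 0 to 10 and from 1 to 17. The lists called ranged from 5 to 8 for the mean, 0 to 5 at 2 h, 2 to 7 at 4 h, 2 to 5 at 8 h, 0 to 9 at 24 h, 3 to 8 at 48 h and 11 to 12 in untreated cells.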

Other observations

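The replicate numbers differed more than the treatments did. With limma, 8254 of 19775 genes (41.7%) were called between them, 5408 higher and 2846 lower in replicate 2. As for TLR2, these tests and the list tests between the numbers measure the spread among arrays, not that between experiments. FOLR1, a folate receptor, was 5.32-fold higher in replicate 2 (7.45 ± 0.46 against 9.86 ± 0.47, SD, n = 10; adjusted p = 8.12e-09) and HAS2, a hyaluronan synthase, 2.86-fold higher (adjusted p = 4.90e-10). SPINT2, a protease inhibitor, was 2.73-fold lower (adjusted p = 9.85e-11), EPCAM, an epithelial adhesion molecule, 2.58-fold lower (1.31e-10) and IFIT2, an interferon-induced gene, 2.30-fold lower (2.73e-09). Interferon response genes were lower in replicate 2 as a list (18 of 50 called lower and 5 higher, camera, adjusted p = 0.000286; 0.0378 with an estimated correlation). NF-kB targets had 18 of 30 members called lower (5.56e-08; 0.328 with an estimated correlation), and ribosomal proteins 50 of 51 called higher (9.59e-20; 0.375 with an estimated correlation). The LPS effect averaged over the 5 times was not called different between the replicate numbers for any gene (limma, 0 genes, 1140 at an unadjusted p under 0.05; adjusted p = 0.962 for CXCL8). Tests at single times, added after the values were seen, had 1 array in each arm. They decide nothing about a difference between the replicate numbers at a time.

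Lists that the LPS comparisons left uncalled at the preset correlation in the mean of 5 times, without the replicate term, included markers of other cell types. Median log2 differences were -0.06 for leukocyte markers, 0.00 for endothelial, 0.01 for neuronal, -0.03 for fibroblast and 0.01 for kidney epithelial markers. They were -0.02 for interferon response genes, 0.02 for Toll-like receptor signalling, 0.05 for its negative regulators, 0.03 for NRF2 targets, 0.02 for p53 targets, 0.06 for the unfolded protein response and -0.02 for metallothioneins. Medians of 0.06 for heat shock genes, 0.05 for immediate early genes, 0.05 for YAP targets, 0.03 for mitosis genes, 0.02 for oxidative phosphorylation, 0.01 for cytokines, -0.01 for the TXNIP list and -0.03 for polyadenylated histone genes were found for others. NF-kB targets (median 0.09) and ribosomal proteins (-0.03) were also uncalled without the term.

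Of the tests that follow, those on replicate 1 alone and on RNA degradation at 48 h were chosen after the result was seen. That of exchanged labels concerns the pair of arrays that stood apart by its values, so it is not independent of those values. NF-kB targets were higher in untreated cells at 48 h than at 2 h. The rise was not confined to the array of replicate 2. In replicate 1 the mean change was 0.355 (SE 0.104 over genes, 22 of 30 genes above 0) against -0.03 for all genes. With the labels of the 48 h arrays of replicate 2 exchanged, the change in replicate 2 was still 0.322 (SE 0.0993 over genes, 22 of 30 genes). Each of these values compares 1 array with 1 array. Their SEs are over genes, which are not independent replicates, so variation between arrays or cultures is not measured and not excluded. More degraded RNA at 48 h was argued against by the 3′ minus 5′ signal of actin and GAPDH, which differed by -0.0380 where the SD of the 20 arrays was 0.151. A response of the cells to time in culture or to the change of medium stays open as a hypothesis. Neither was tested, since every array of a time shares the age of the culture and the time since that change.

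TLR2 was lower in replicate 2 than in replicate 1, by -1.66 (SE 0.10). The difference was -1.70 (SE 0.10) after quantile normalization. The deposited arrays already had nearly equal distributions, so that step could change little and cannot decide whether earlier processing gave the difference. With the 3′ minus 5′ signal as a covariate the TLR2 difference was -1.77 (SE 0.17), so RNA degradation as measured by this signal does not account for it. No biological explanation was tested, and the cause may lie in the cells or in how the arrays of each replicate were made.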
